A study of Mus musculus with 9 samples.

How the data were processed

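Bulk RNA sequencing of cancer cells from 9 mouse lung tumour samples was analysed. Per the labels' protocols, tumours were started by instilling adenoviral Cre under the CCSP promoter into the trachea, the lungs of moribund mice were dissociated with enzymes, cancer cells were collected by FACS, and libraries were made from polyA RNA with a low-input SMART-seq kit. All mice carried 2 floxed Trp53 alleles and a Cre-activated tdTomato reporter on a mixed strain background. The sort gate is not given in the sources used here. Groups were taken from the genotype label: KP (Smarca4 wild type, n = 4), KPS-HET (1 floxed Smarca4 allele, n = 2) and KPS (2 floxed alleles, n = 3). Replicates were numbered within a group in the order of the samples, so the numbers pair nothing. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples.

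The values are estimated counts per gene as the authors deposited them, with fractions and with no scaling between libraries. Per the submitters' processing notes they were made with RSEM 1.3.1, Bowtie 1.2.3 and the mouse build mm9. The gene annotation, strand setting and filters are not given in the sources used here. Reads from near-identical paralogs are divided between them by the estimation, and overlapping or antisense genes cannot be told apart without strand, so single members of such families are uncertain. The table held 23224 gene symbols. Of these, 25 were dates in place of symbols, of which 21 were tested under the deposited name and none is named in the text, and 14 of the tested genes had the same values as another gene. The annotation table at hand is for GRCm38.p6, another build, so no coordinates are given and it served only for the order of genes along a chromosome.

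Counts were rounded to whole numbers (a change of at most 0.5 per value). Library totals ran from 12607500 to 37114400. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 15663 genes and removed 7561. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with TMM scaling and robust estimates, 1 coefficient per group over all 9 libraries (6 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is called where its adjusted p lies below that threshold. The common biological coefficient of variation was 0.430. Adjusted p-values of single genes come from edgeR unless another tool is named. Levels are TMM-scaled CPM with the SD over libraries, and fold changes are on the log2 scale with their SE. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group (0.0382 CPM in KP, 0.0819 in KPS-HET and 0.0376 in KPS). Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only.

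Before the data were examined, the groups, the tests, the alternatives, 37 gene lists and the rule for naming genes were fixed. The lists were BAF complex subunits, markers of alveolar type 2, alveolar type 1, club and ciliated cells, lung epithelial transcription factors, gastric and gut endoderm, embryonic and metastasis, mesenchymal transition, epithelial junction and keratin, transitional cell state, mitosis, DNA replication, oxidative phosphorylation, glycolysis and hypoxia, NRF2 target, interferon response, MHC class I, MHC class II, RAS-MAPK output, p53 target, WNT target, YAP-TEAD target, NOTCH pathway, fatty acid and cholesterol synthesis, neuroendocrine, basal and squamous, immediate early and dissociation, and sex-linked genes, and markers of macrophages and monocytes, neutrophils, T and NK cells, B cells, endothelium, fibroblasts, mesothelium and red blood cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, 33 lists in all, adjusted over those lists. The rule named the targeted genes, the 10 called genes with the highest and the 10 with the lowest fold change between KPS and KP (5 and 5 for the other comparisons, or the 3 smallest p in each direction where none was called), with a mean of at least 5 CPM and no overlap between the groups, and up to 4 members of each list with the smallest p. Predicted gene models were left out of the fold change part.

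The methods were tested on counts simulated for all 9 libraries, from the mean and spread of each gene over all 9. For KPS against KP 15262 genes were tested, with 100 genes changed by each fold. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery at lower levels was not simulated. edgeR recovered 39% of genes changed 2-fold and 84% of those changed 4-fold, with 8 false calls among 139. limma-voom recovered 35% and 77%, with 4 false among 124. DESeq2 1.42.0 (15205 genes) recovered 59% and 94%, but 51 of its 217 calls were false (23.5%), well over the nominal share, which bears on its larger counts of calls. The list test picked out a simulated raised list and passed over an unchanged one. Simulated genes were drawn independently, so this does not test the preset correlation for lists whose members vary together. No pair of libraries was alike within sampling noise: the lowest chi-square per degree of freedom within a group was 44.0.

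Gene results were recomputed with RLE or upper-quartile factors, with no filter on low counts or a strict one (10 CPM in 2 libraries), with DESeq2, with limma-voom and sample weights, without robust estimates, with the libraries of the 2 groups alone, and without each library in turn. List tests were recomputed with an estimated correlation in camera, with RLE factors and without each library in turn. Fits with the sex of the library or the macrophage marker level as a term (genes and lists) and with all libraries thinned to the smallest total (genes) were chosen after seeing the data. The labels give no batch, date or sex, and sex was read from the level of Xist against that of the Y-linked gene Ddx3y. Results for some genes are not reported here. Reads and coordinates were not used here, so the recombined Smarca4 exons were not examined.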

Results

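Gene expression was measured by bulk RNA sequencing in cancer cells sorted from mouse lung tumours that differed in the number of conditional Smarca4 alleles. Smarca4 encodes BRG1, an ATPase of the BAF chromatin remodelling complex. All tumours carried conditional Trp53 alleles and were started by adenoviral Cre under the CCSP promoter, which is active in club cells of the airway. Wild-type tumours (KP) gave 4 libraries, tumours with 1 floxed Smarca4 allele (KPS-HET) gave 2, and tumours with 2 floxed alleles (KPS) gave 3. Library totals ran from 15275300 to 29231600 estimated counts in KP, from 12607500 to 22705400 in KPS-HET and from 21368900 to 37114400 in KPS. On the first principal component of log2 CPM (32.4% of the variance) the KPS libraries lay between 71.8 and 89.3. The KP libraries lay between -51.2 and -39.9 on it and the KPS-HET libraries between -39.4 and -14.2.

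Smarca4 mRNA was lower in KPS than in KP. It stood at 126 ± 12.0 CPM in KP (SD, n = 4), 86.8 ± 14.7 CPM in KPS-HET (SD, n = 2) and 47.7 ± 7.84 CPM in KPS (SD, n = 3). The fall in KPS against KP was -1.40 ± 0.15 on the log2 scale (SE; adjusted p = 0.0021), with every KPS library below every other library. KPS-HET differed from KP by -0.53 ± 0.17 (adjusted p = 0.974) and KPS from KPS-HET by -0.86 ± 0.18 (adjusted p = 0.055), and neither difference passed the test. The counts cover the whole gene, so reads from exons outside the floxed part may remain in them. Whether the remaining reads came from recombined alleles, from alleles left intact or from other cells in the sort was not tested. Trp53, floxed in all 3 groups, was low throughout, at 10.3 ± 2.87 CPM in KP, 8.15 ± 2.33 in KPS-HET and 15.1 ± 6.15 in KPS (adjusted p = 0.385 for KPS against KP).

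**Figure D1:**
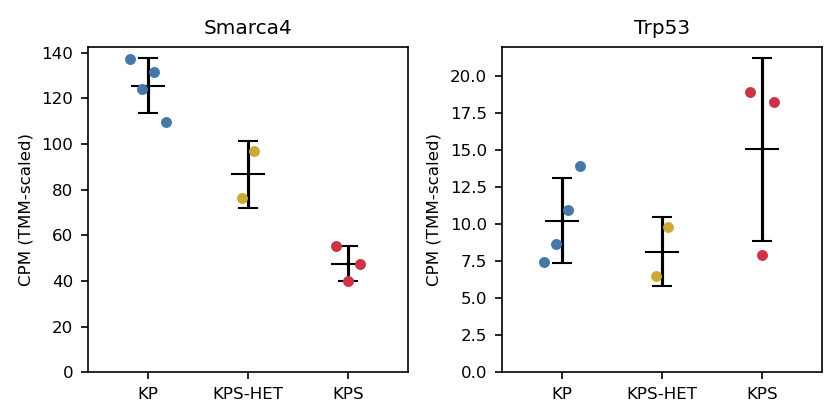
TMM-scaled level (CPM) of Smarca4 and Trp53 in each library (points) with the group mean and SD (black bars), for KP (n = 4), KPS-HET (n = 2) and KPS (n = 3). Smarca4 averaged 126 CPM in KP, 86.8 in KPS-HET and 47.7 in KPS.

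The main comparison asked how the cancer cells of KPS tumours differed from those of KP tumours. Reg1 and Reg3b, secreted lectins of the regenerating family, had no counts in any KP library and averaged 21.5 ± 19.95 and 14.2 ± 4.82 CPM in KPS (SD, n = 3). Against a floor of 3 counts over the KP libraries they were at least 467.6-fold and at least 349-fold higher. Alb, which encodes albumin, fell from 204 ± 274 CPM in KP to 4.39 ± 3.70 CPM in KPS, and Acta2, smooth muscle actin, fell from 120 ± 68.9 to 3.34 ± 1.14 CPM. Cyp2c68, a cytochrome P450, averaged 25.6 ± 29.8 CPM in KP and had no counts in any KPS library, at least 661.6-fold lower. Single libraries weighed on these bounds. Reg1 was at least 236-fold higher without KPS replicate 2, 293-fold without KP replicate 4 and 764.6-fold without KPS replicate 1, and Reg3b at least 219-fold higher without KP replicate 4. Cyp2c68 was at least 327-fold lower without KP replicate 3 and 368.6-fold without KPS replicate 1. With limma-voom neither Reg1 (adjusted p = 0.124) nor Cyp2c68 (adjusted p = 0.163) was called.

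In all, 1134 of 15663 genes tested differed between KPS and KP, 621 higher and 513 lower in KPS. Of these, 709 differed by more than 2-fold. In 1114 of the 1134 the libraries of the groups did not overlap. Over all genes tested 21.8% did not overlap, where chance gives 5.71%. With 1 library left out, 505 genes passed without KPS replicate 3, 512 without KP replicate 1, 673 without KP replicate 4, 694 without KPS replicate 2, 738 without KP replicate 2, 798 without KPS replicate 1 and 886 without KP replicate 3. DESeq2, which made 51 false calls among 217 on simulated counts, called 2280, and a fit with the macrophage marker level as a term, chosen after seeing the data, called 295.

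Among the other genes with the highest fold changes were Reg3g, an antimicrobial lectin of club cells and gut (log2 fold change 5.50 ± 0.85, SE), and Serpinb1a, an inhibitor of neutrophil proteases (5.50 ± 0.63). The coagulation factor gene F5 (6.32 ± 1.12), the pancreatic polypeptide receptor gene Ppyr1 (6.28 ± 1.25), the sulfotransferase gene Sult1c2 (5.75 ± 1.21), Fxyd6 (5.71 ± 0.59) and the matrix gene Matn3 (5.67 ± 0.79) also rose. Their adjusted p ran from 0.0017 for Fxyd6 to 0.025 for Sult1c2. In the other direction Clstn3 fell by 7.83 ± 0.79 and Habp2, a plasma protease, fell by 7.62 ± 0.88. The adhesion receptor gene Gpr128 fell by 7.47 ± 1.31, Tmem27 fell by 6.60 ± 1.14, Tmed6 fell by 4.54 ± 1.13, the chemokine gene Pf4 fell by 4.49 ± 0.66 and the glypican gene Gpc3 fell by 4.31 ± 0.61. Alb (-5.50 ± 1.36, adjusted p = 0.046) and Tmed6 (adjusted p = 0.042) were closest to the threshold. Without 1 library or under other settings, Alb lost its call in 9 of 15 alternative fits and Tmed6 in 7 of 15. Of these, leaving out KP replicate 1, KP replicate 4 or any KPS library ended the Alb call (adjusted p = 0.059 to 0.112), and leaving out KP replicate 1, 3 or 4 or KPS replicate 1 or 2 ended that of Tmed6 (0.060 to 0.106). Leaving out KP replicate 1, KPS replicate 2 or KPS replicate 3 ended the calls of Ppyr1 (0.054 to 0.061) and Sult1c2 (0.053 to 0.072), and leaving out KP replicate 4 that of Sult1c2 (0.055). With limma-voom Clstn3 (0.114), Gpr128 (0.145), Tmem27 (0.102) and Habp2 (0.052) were not called. Over all alternative fits and tools Ppyr1 lost its call in 4 of 15 (highest adjusted p 0.113) and Sult1c2 in 5 of 15 (0.208).

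Several of these fold changes moved by more than 1.5-fold without 1 library. Where at most 3 counts were left in a group, a bound or a ratio with its 95% counting interval stands in place of the fitted value. Without KPS replicate 1 Habp2 was at least 525.9-fold and Tmem27 at least 395-fold lower, and Clstn3 was 353-fold lower (121 to 1715). Without KPS replicate 2 Gpr128 was 1247-fold lower (224 to 49301), and without KP replicate 3 Ppyr1 was 561-fold higher (155 to 4633). The log2 fold changes without KP replicate 3 were -6.22 for Gpr128, -5.98 for Tmem27, -3.95 for Alb, -3.76 for Pf4 and -3.61 for Gpc3. Alb stood at -6.52 without KPS replicate 1, Tmed6 at -5.89 without KPS replicate 3, Reg3g at 4.87 without KPS replicate 2 and F5 at 8.88 without KP replicate 1.

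**Figure D2:**
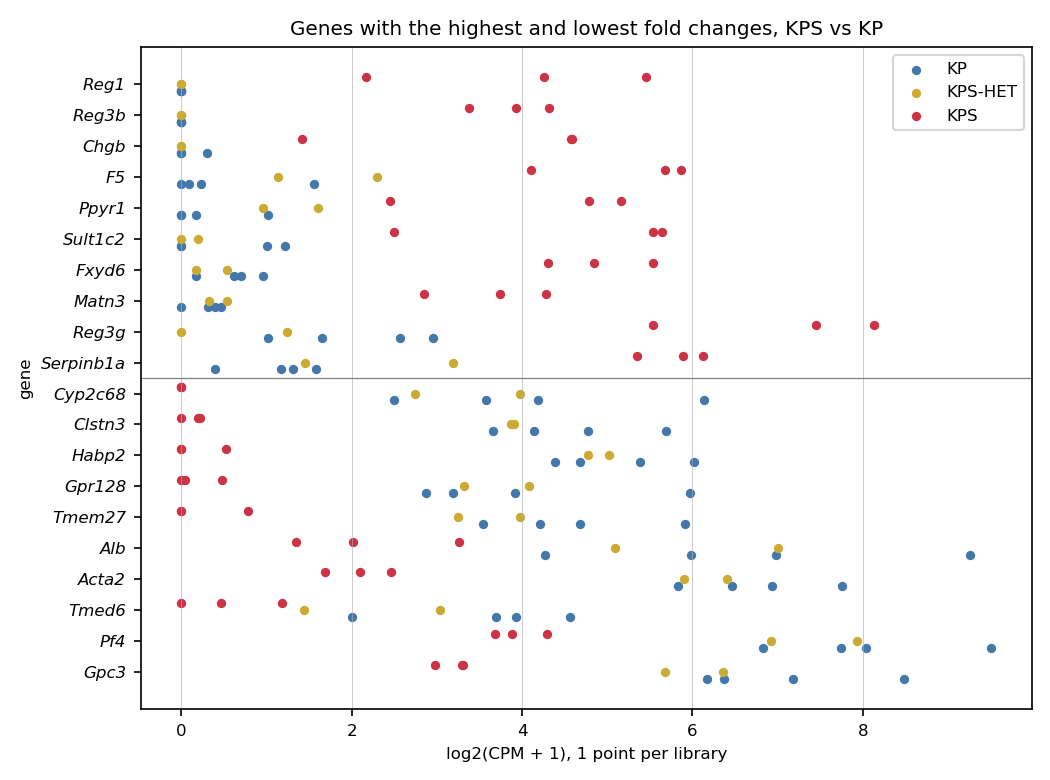
Level of the 10 genes with the highest and the 10 with the lowest fold change between KPS and KP, as log2(CPM + 1), with 1 point per library of KP (n = 4), KPS-HET (n = 2) and KPS (n = 3). For each gene the KPS libraries lie apart from the KP libraries, which was a condition for naming it.

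Of 20 alveolar type 2 cell markers 5 fell and none rose in KPS over all genes tested, while 11 fell and 1 rose when adjusted over the list alone. The surfactant protein gene Sftpb fell by 0.70 ± 0.17 (4537 ± 940 CPM in KP, 2792 ± 178 in KPS), Fabp5 fell by 1.16 ± 0.22, Dram1 fell by 0.79 ± 0.17 and the complement gene Hc fell by 2.26 ± 0.48. The list as a whole was lower (camera adjusted p = 1.81e-06, median log2 fold change -0.80; adjusted p = 0.594 with an estimated correlation). Of 22 lung epithelial transcription factors 4 fell, among them Nkx2-1 (-0.68 ± 0.16), the lineage factor of lung epithelium, Cebpa (-0.65 ± 0.14), Elf5 (-1.40 ± 0.34) and Id2 (-1.41 ± 0.36), with 3 up and 7 down when adjusted over the list alone. That list was not called (camera adjusted p = 0.547), and its median (0.11) and mean (0.24) log2 fold changes were positive where the direction of the test was down. Club cell markers gave 3 rises (Reg3g, Hp and Aldh1a1) and 1 fall (Gsta3) among 20 members, with 4 up and 4 down when adjusted over the list alone (camera adjusted p = 0.406). Hp, haptoglobin, rose from 939 ± 273 to 2633 ± 817 CPM. Alveolar type 1 markers gave 2 rises among 17, Cldn18 (1.19 ± 0.30) and Ahnak (0.78 ± 0.14), with 2 up and 2 down adjusted over the list alone (camera adjusted p = 0.336), and none of 13 ciliated cell markers changed by either count (camera adjusted p = 0.431). Of 15 alternative fits, Id2 and Cldn18 lost their calls in 9, Sftpb in 8, Nkx2-1 in 6, Elf5 in 5, Aldh1a1 in 4, Cebpa, Dram1 and Hc in 3 and Ahnak in 1 (highest adjusted p 0.118).

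Of 22 gastric and gut endoderm genes 4 rose and 4 fell (5 up and 6 down adjusted over the list alone; camera adjusted p = 0.947, direction down, with a median of 0.04 and a mean of 0.27). The trefoil factor gene Tff2 rose from 0.383 ± 0.221 to 7.07 ± 3.42 CPM and the galectin gene Lgals4 from 20.6 ± 6.93 to 85.8 ± 53.3 CPM. Vil1, villin of the brush border, fell by 3.88 ± 0.82 (-4.71 without KPS replicate 1) and Pgc, a pepsinogen, fell by 2.23 ± 0.51. Of 11 basal and squamous genes Sprr1a rose (1.93 ± 0.36) and Ivl, involucrin, fell by 2.21 ± 0.33, with 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.980, direction down, with a median of 0.26 and a mean of 0.69). Both encode precursors of the cornified envelope. Vil1 lost its call in 6 of 15 alternative fits and Lgals4 and Pgc in 5 (highest adjusted p 0.117).

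Of 15 neuroendocrine genes tested 5 rose and none fell, and 6 rose when adjusted over the list alone (camera adjusted p = 1.30e-04, median log2 fold change 2.73; adjusted p = 0.594 with an estimated correlation). Neurod1, a transcription factor of neuroendocrine cells, had 0 counts over the KP libraries and 4.29 ± 2.40 CPM in KPS, at least 101-fold higher. Scg3, a granin, also had 0 counts in KP and 1.21 ± 0.840 CPM in KPS, at least 28.9-fold higher. Chga stood at 0.105 ± 0.211 CPM in KP and 5.26 ± 0.320 in KPS (adjusted p = 0.037), and Chgb at 0.0574 ± 0.115 and 15.9 ± 12.3 CPM (adjusted p = 0.012). With genes at 0 counts set to their bound the median log2 fold change of the list was again 2.73. Levels in KPS remained low, and Scg3 and Chga each lost their call in 6 alternative fits. Without KP replicate 4 the bounds were 63.5-fold for Neurod1 and 18.1-fold for Scg3, which then was not called (adjusted p = 0.071). Chga was at least 107-fold higher without KP replicate 2 and Chgb at least 266-fold higher without KP replicate 3, the KP libraries that held all of their counts in KP. Chgb was not called with limma-voom (adjusted p = 0.187).

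Of 17 targets of NRF2, the oxidative stress response factor, 6 rose and none fell, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.10e-04, median log2 fold change 0.38; adjusted p = 0.594 with an estimated correlation). The pentose phosphate enzyme genes Pgd (1.65 ± 0.21) and G6pdx (1.19 ± 0.16) rose from 207 ± 26.3 to 647 ± 225 CPM and from 146 ± 22.3 to 332 ± 63.6 CPM. Srxn1, sulfiredoxin, rose by 1.82 ± 0.27 and the glutathione transferase gene Gsta4 by 2.48 ± 0.33, to 1227 ± 351 CPM. Glycolysis and hypoxia genes gave 2 rises, Hk1 (0.87 ± 0.14) and Pfkfb3 (1.37 ± 0.32; 0.74, adjusted p = 0.084, without KPS replicate 1), and 1 fall, P4ha1 (-0.86 ± 0.17), among 23, with the same numbers adjusted over the list alone (camera adjusted p = 0.922). Among 31 oxidative phosphorylation genes 1 rose, Cox7a2 (0.48 ± 0.13), and none adjusted over the list alone (camera adjusted p = 0.585). Cox7a2 lost its call in 10 of 15 alternative fits, Pfkfb3 in 7 and P4ha1 in 1 (highest adjusted p 0.158).

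RAS-MAPK output genes were lower as a list (camera adjusted p = 0.033, median -0.42; adjusted p = 0.594 with an estimated correlation). Spry2 (-1.10 ± 0.18) and Etv4 (-1.04 ± 0.20) fell among 17, and 1 rose and 4 fell adjusted over the list alone. YAP-TEAD targets were higher as a list (camera adjusted p = 0.033, median 0.57; adjusted p = 0.594 with an estimated correlation). Of 13, Ctgf (2.18 ± 0.53), Crim1 (1.55 ± 0.29), F3 (1.35 ± 0.25) and Nt5e rose and Nuak2 fell by 0.91 ± 0.18, with 6 up and 2 down adjusted over the list alone. Immediate early and dissociation genes were lower as a list (camera adjusted p = 0.013, median -0.45; adjusted p = 0.667 with an estimated correlation). Egr1 (-1.01 ± 0.19), Ier2 (-1.04 ± 0.22) and Nr4a1 (-0.68 ± 0.16) fell and Socs3 (1.08 ± 0.20) and Klf4 rose among 18, with 2 up and 8 down adjusted over the list alone. Mesenchymal transition genes were higher as a list (camera adjusted p = 0.013, median 1.22; adjusted p = 0.594 with an estimated correlation). Tgfb2 (1.87 ± 0.39) and S100a4 (2.13 ± 0.54) rose and Sparc (-0.83 ± 0.16) fell among 16, with 5 up and 1 down adjusted over the list alone. In the same comparison the fibroblast and endothelial markers, not called as lists, had medians of 2.52 and 1.76, with 8 of 10 and 11 of 12 fold changes positive. Without KPS replicate 3 Ctgf stood at 1.15 (adjusted p = 0.104) and S100a4 at 1.49 (adjusted p = 0.173). In the epithelial junction and keratin list the adherens junction gene Cdh1 rose from 757 ± 127 to 1535 ± 219 CPM and the tight junction gene Tjp1 by 0.60 ± 0.16. No other of its 20 members was called, with 2 up adjusted over the list alone (camera adjusted p = 0.336). Of 16 transitional cell state genes Sfn (1.39 ± 0.16), Itgb6 (1.36 ± 0.23) and Plaur rose, while Slc4a11 (-1.52 ± 0.35) and Areg fell. Adjusted over the list alone 6 were up and 2 down (camera adjusted p = 0.119). Of 15 alternative fits, Tjp1 lost its call in 9, S100a4 in 7, Ctgf and Nr4a1 in 6, Slc4a11 in 4, Tgfb2 and Ier2 in 3, Plaur and Sparc in 2 and Crim1, Egr1, Etv4, Nuak2 and Socs3 in 1 (highest adjusted p 0.173).

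MHC class I genes were higher as a list (camera adjusted p = 0.012, median log2 fold change 0.58; adjusted p = 0.594 with an estimated correlation), with Tapbp (0.95 ± 0.13), Tap2 (0.66 ± 0.14) and H2-D1 (0.58 ± 0.13) up among 13, and 8 up and 1 down adjusted over the list alone. Interferon response genes were higher as a list (camera adjusted p = 0.033, median 0.50; adjusted p = 0.786 with an estimated correlation), with 2 up among 22, of which Isg15 had a log2 fold change of 1.95 ± 0.46, and 3 up adjusted over the list alone. MHC class II genes were lower as a list (camera adjusted p = 0.033, median -0.61; adjusted p = 0.786 with an estimated correlation). Ciita, their master regulator, fell by 1.33 ± 0.32 among 9, and Ctss, a lysosomal protease abundant in macrophages, rose (3.70 ± 0.93; 2.08, adjusted p = 0.131, without KPS replicate 1), with 1 up and 2 down adjusted over the list alone. H2-Aa stood at 487 ± 178 CPM in KP and 278 ± 62.4 in KPS (adjusted p = 0.106) and Cd74 at 2527 ± 917 and 1500 ± 400 CPM (adjusted p = 0.147). Ctss lost its call in 9 of 15 alternative fits, H2-D1 in 7 and Tap2, Isg15 and Ciita in 5 (highest adjusted p 0.152). Leaving out 1 library ended the list calls of interferon response (adjusted p = 0.312 without KPS replicate 3, 0.111 without KP replicate 3 and 0.073 without KP replicate 1) and of MHC class II (0.326 without KPS replicate 3, 0.139 without KP replicate 2 and 0.066 without KP replicate 3). It also ended those of RAS-MAPK (0.179 without KPS replicate 3, 0.085 without KP replicate 4, 0.066 without KP replicate 3 and 0.053 without KPS replicate 1), YAP-TEAD (0.118 without KP replicate 2 and 0.053 without KPS replicate 2), immediate early (0.068 without KP replicate 3) and MHC class I genes (0.053 without KPS replicate 1).

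**Figure D3:**
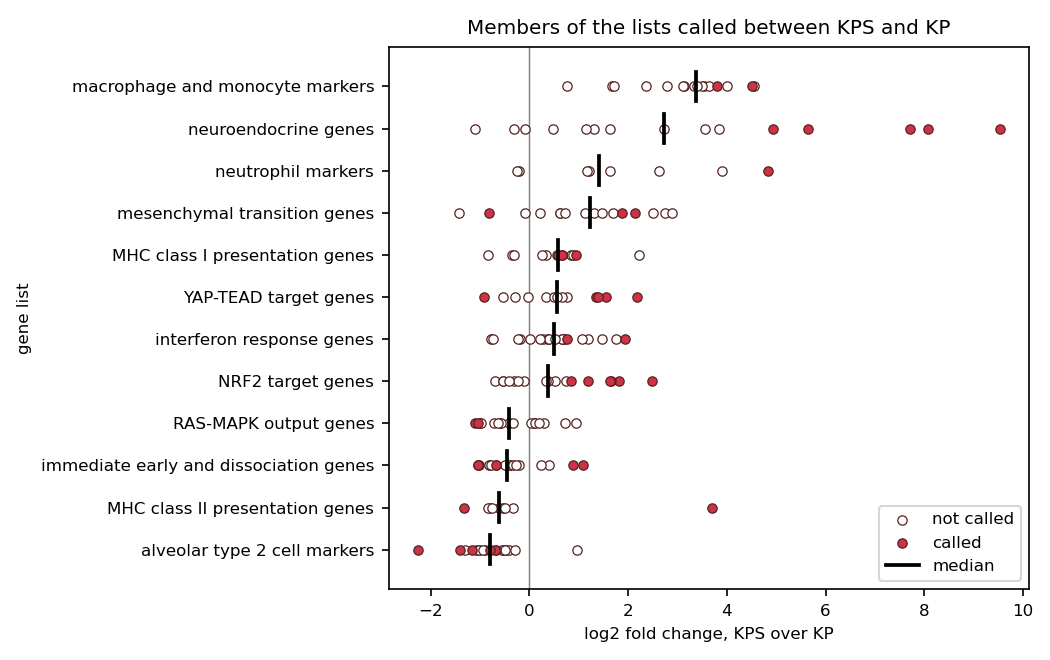
Log2 fold changes, KPS over KP, of the members of the 12 lists called with the preset correlation. Filled points are genes with adjusted p below 0.05, open points are other members and black bars are list medians, which run from -0.80 for alveolar type 2 cell markers to 3.37 for macrophage and monocyte markers.

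All 16 macrophage and monocyte markers had positive fold changes in KPS, of which Marco (4.52 ± 1.10) and Chi3l3 (3.81 ± 0.96) passed over all genes and 12 when adjusted over the list alone. Without KPS replicate 1 neither passed over all genes, with Marco at 1.83 (adjusted p = 0.157) and Chi3l3 at 2.46 (adjusted p = 0.152). Chi3l3 lost its call in 9 of 15 alternative fits and Marco in 7 of 14 (highest adjusted p 0.243). The list was higher (camera adjusted p = 7.89e-06, median 3.37; adjusted p = 0.594 with an estimated correlation). Their mean log2 CPM was 5.29 in KPS replicate 1, 3.11 in KPS replicate 3 and 1.93 in KPS replicate 2. It was 3.32 in KPS-HET replicate 1, 0.662 in KPS-HET replicate 2 and between 0.576 and 1.46 in KP. Chi3l3 thus averaged 1856 ± 1958 CPM in KPS. The common leukocyte gene Ptprc stood at 27.2 ± 33.6 CPM in KPS and 2.34 ± 1.06 in KP (adjusted p = 0.050) and was not called. Its log2 fold change of 3.53 ran from 1.73 to 4.03 without 1 library. The MHC class I, interferon response, mesenchymal and neutrophil lists above and below rose in the same comparison. With the macrophage marker level as a term in the fit the adjusted p was 0.071 for the MHC class I, neutrophil and immediate early lists, 0.594 for the mesenchymal, 0.304 for the RAS-MAPK and 0.052 for the YAP-TEAD list. The interferon response, MHC class II and NRF2 (adjusted p = 0.034 each), alveolar type 2 (0.015) and neuroendocrine (2.44e-04) lists were called with the term. It was 0.973 for the macrophage list itself, which supplied the term.

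Neutrophil markers were higher as a list (camera adjusted p = 0.033, median 1.42; adjusted p = 0.594 with an estimated correlation). Its 1 called member over all genes was Ltf, lactoferrin, which is also secreted by epithelia and rose from 241 ± 172 to 6891 ± 5031 CPM, and 2 of 8 rose adjusted over the list alone. S100a8, among the most abundant neutrophil transcripts, stood at 10.9 ± 7.42 CPM in KPS. Its log2 fold change was 1.63 (adjusted p = 0.305) and ran from 1.09 to 2.85 without 1 library. S100a9, of the same list, had a larger log2 fold change of 3.90 ± 1.23 (adjusted p = 0.088) and was not called either. Of the 8 members 6 had positive fold changes. Of 12 endothelial markers Ramp2 rose (3.61 ± 0.68; 1 up and 1 down adjusted over the list alone, camera adjusted p = 0.154) and of 10 fibroblast markers Col1a1 rose (2.64 ± 0.69; 1 up adjusted over the list alone, camera adjusted p = 0.345), from 1.10 and 1.16 CPM in KP. Without KPS replicate 3 Col1a1 stood at 1.45 (adjusted p = 0.274) and Ltf at 4.22 in place of 4.84. Lists with fewer than 5 members tested had no list test. Among them Msln, a mesothelial gene also expressed in carcinomas, rose from 257 ± 173 to 1664 ± 751 CPM (1 of 3 mesothelial markers), and the haemoglobin gene Hba-a1 rose from 5.64 ± 5.33 to 59.2 ± 15.8 CPM (1 of 2 red blood cell genes; log2 fold change 3.41, and 4.06 without KP replicate 3). Cd79b fell by 1.28 ± 0.29 (1 of 3 B cell markers), and none of 4 T and NK cell markers changed. Adjusted over the list alone these counts were again 1, 1, 1 and 0. Col1a1 lost its call in 8 of 14 alternative fits, and of 15 Cd79b and Hba-a1 lost theirs in 6, Msln in 4, Ltf in 3 and Ramp2 in 1 (highest adjusted p 0.274).

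Proliferation lists held no called gene by either count, with 20 mitosis genes (camera adjusted p = 0.947) and 22 DNA replication genes (camera adjusted p = 0.802). Of 25 BAF complex subunits Smarca4 fell and Arid2 rose (0.48 ± 0.11), also when adjusted over the list alone (camera adjusted p = 0.954). Among 24 embryonic and metastasis genes the transcription factor gene Runx2 rose (1.70 ± 0.42) and Pthlh, which encodes a parathyroid hormone-like factor, fell by 2.58 ± 0.59 (-3.25 without KPS replicate 1), with 1 up and 4 down adjusted over the list alone (camera adjusted p = 0.512). Of 11 NOTCH pathway genes Notch1 (-1.23 ± 0.30) and Jag1 (-0.67 ± 0.15) fell, also when adjusted over the list alone (camera adjusted p = 0.385). Of 17 p53 targets Ccng1 (0.63 ± 0.15) and Trp53inp1 (0.79 ± 0.19) rose and Fas (-1.18 ± 0.31) fell, with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.312). Of 11 WNT targets Tcf7 rose (3.55 ± 0.72; 2.84, adjusted p = 0.081, without KPS replicate 3), with 2 up adjusted over the list alone (camera adjusted p = 0.385). No gene among 21 of fatty acid and cholesterol synthesis (camera adjusted p = 0.071) or among 5 sex-linked genes (camera adjusted p = 0.431) changed by either count. In the order median, mean and test, the BAF list (0.05, 0.01, down), the embryonic list (-0.24, 0.12, down) and the mitosis list (0.00, 0.03, up) also differed in sign. Nt5e, Klf4 and Areg above, and the called members Lgi3 (alveolar type 2, lower), Foxa3 and Gkn2 (gut, lower), Gkn3 and Tff1 (gut, higher), Gsr and Abcc1 (NRF2, higher) and Resp18 (neuroendocrine, higher), lie outside the naming rule and were chosen after their values were seen. Of 15 alternative fits, Fas and Trp53inp1 lost their calls in 7, Arid2, Ccng1, Notch1 and Runx2 in 6, Pthlh in 5, Jag1 in 4 and Tcf7 in 3 (highest adjusted p 0.161). Of 92 named genes called between KPS and KP, 34 were called without each library in turn. The calls ended were 49 without KPS replicate 3, 44 without KP replicate 1, 34 without KP replicate 4, 31 each without KPS replicate 1 and KP replicate 2, 27 without KPS replicate 2 and 25 without KP replicate 3.

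Comparing KPS with KPS-HET asked what separated tumours with 2 floxed alleles from those with 1. Reg3b had no counts in KPS-HET and was at least 163-fold higher in KPS. Reg3g rose from 0.685 ± 0.968 CPM in KPS-HET (SD, n = 2) to 166 ± 117 CPM in KPS (SD, n = 3) and Fxyd6 from 0.290 ± 0.229 to 30.6 ± 13.6 CPM. Kng1, kininogen, rose by 3.92 ± 0.74 and the GTPase gene Arl14 by 3.30 ± 0.61. Habp2 fell by 7.26 ± 0.91, Clstn3 fell by 6.90 ± 0.81, Acta2 fell by 4.41 ± 0.53, Pf4 fell by 3.63 ± 0.68 and Palm3 fell by 3.62 ± 0.52. In all 146 genes were called, 82 higher and 64 lower in KPS. All 146 had libraries that did not overlap. Over all genes tested 36.4% did not overlap, where chance gives 20%. Few genes were called without 1 of the KPS-HET libraries, which leaves a lone sample in that group. The called genes' log2 fold changes then had slopes of 1.02 (without KPS-HET replicate 1) and 1.01 (without replicate 2) on those with all libraries. These genes had been called with both KPS-HET libraries, and the fits share the KPS libraries. Slopes near 1 were therefore likely and are no independent evidence. The count was 42 without KPS replicate 2 and 61 without KPS replicate 3. It was 15 in a fit of the libraries of these 2 groups, 231 with the strict filter and 991 with DESeq2. None of the 10 genes above was called without KPS-HET replicate 1 (adjusted p = 0.075 to 0.285). Without KPS-HET replicate 2 Acta2 and Clstn3 were called and the other 8 were not (0.060 to 0.219). Reg3b was at least 57.5-fold higher without KPS-HET replicate 1 and at least 104-fold without KPS-HET replicate 2. The log2 fold change of Fxyd6, 6.82, was 6.02 without the former, and without the latter Fxyd6 was 237-fold higher (95% counting interval 81.1 to 1151). Reg3b, Reg3g, Kng1, Arl14 and Pf4 also lost their calls without KPS replicate 2 (adjusted p = 0.081 to 0.104) or KPS replicate 3 (0.058 to 0.099), as did Palm3 without KPS replicate 3 (0.053) and Arl14 and Pf4 without KPS replicate 1 (0.054 and 0.089). Reg3g was at least 613-fold higher without KPS-HET replicate 1, and its log2 fold change of 7.68 was 6.91 without KPS-HET replicate 2 and 7.09 without KPS replicate 2. Without KPS replicate 1 Habp2 was at least 439.5-fold lower and Clstn3 205-fold lower (69.9 to 999).

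The NRF2 targets Pgd (1.71 ± 0.27), G6pdx (1.15 ± 0.20), Srxn1 (1.76 ± 0.34) and Gsta4 (2.34 ± 0.42) rose in KPS over KPS-HET, 4 of 17 members, with 8 up and 1 down adjusted over the list alone (camera adjusted p = 9.83e-04; adjusted p = 0.739 with an estimated correlation). No single neuroendocrine, alveolar type 2, ciliated, YAP-TEAD or macrophage gene was called over all genes. As lists, neuroendocrine genes (adjusted p = 9.83e-04, median 2.06), YAP-TEAD targets (adjusted p = 0.0043, median 0.58) and macrophage markers (adjusted p = 0.023, median 1.42) were higher. Alveolar type 2 markers (adjusted p = 0.0035, median -0.55) and ciliated cell markers (adjusted p = 0.0035, median -0.81) were lower. With an estimated correlation these had adjusted p = 0.615 for YAP-TEAD targets and adjusted p = 0.739 for the other 4. Adjusted over the list alone, 3 neuroendocrine genes were up, 6 YAP-TEAD targets were up and 1 down, 1 alveolar type 2 marker was down and no ciliated or macrophage marker passed. Without KPS-HET replicate 1 the alveolar type 2 (adjusted p = 0.273), YAP-TEAD (0.076) and NRF2 (0.061) lists were not called. Without KPS replicate 1 the macrophage (0.574), alveolar type 2 (0.119) and ciliated (0.052) lists were not, and without KPS-HET replicate 2 the macrophage list was not (0.656). With the macrophage term, chosen after seeing the data, the macrophage list was not called (0.815) and the other 5 were. Beside Reg3g, a club cell marker, Cdh1 (1.07 ± 0.21), Sfn (1.44 ± 0.21), Hk1 (1.15 ± 0.17) and Tapbp (0.97 ± 0.16) also rose, the 1 called member each of the junction, transitional, glycolysis and MHC class I lists. None of these and the NRF2 targets above was called without KPS-HET replicate 1 or without KPS-HET replicate 2. Of 13 alternative fits, Cdh1 and Srxn1 lost their calls in 8, G6pdx, Gsta4, Hk1 and Tapbp in 5, Pgd in 4 and Sfn in 3, with a highest adjusted p from 0.184 for Sfn to 0.333 for Cdh1. The other 27 lists tested were not called. Among these, median and mean differed in sign for club (-0.27, 0.14), embryonic (-0.21, 0.37) and basal and squamous genes (-0.15, 0.46), each with the test down. For lung transcription factors both were positive (0.15, 0.16) with the test down.

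KPS-HET against KP asked whether 1 floxed allele was enough for a difference. No gene passed with edgeR, whose smallest adjusted p was 0.974. An unadjusted p below 0.05 was found for 627 of 15663 genes, no more than chance gives. The libraries of the groups did not overlap for 13.4% of the genes tested, where chance gives 13.3%. With 2 KPS-HET libraries, changes may be missed, and not only small ones. The mesothelial marker Upk1b had 0 counts in KPS-HET, at least 98.6-fold lower than in KP, and was not called. Recovery of known changes was simulated for KPS against KP only. DESeq2 called 2 genes and limma-voom none. The genes with the smallest p in edgeR, none of them called by it, were Blnk, Vps13c and Tead1 on the higher side and Mpi, Hibadh and Nat6 on the lower. Blnk and Vps13c were the 2 called by DESeq2 (adjusted p = 0.045 each). Tead1, a DNA-binding partner of YAP, stood at 17.8 ± 1.27 CPM in KP, 34.4 ± 1.13 in KPS-HET and 17.6 ± 3.44 in KPS. Mpi, a mannose phosphate isomerase, stood at 58.3 ± 9.42, 33.1 ± 2.59 and 33.2 ± 2.94 CPM. Hibadh, an enzyme of valine breakdown, stood at 259 ± 22.2, 174 ± 7.94 and 161 ± 12.6 CPM.

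Of the lists, 6 were called between KPS-HET and KP with the preset correlation although none of their members was called over all genes or adjusted over the list alone. Immediate early and dissociation genes (adjusted p = 4.28e-08, median -0.46), alveolar type 2 markers (adjusted p = 0.0030, median -0.30) and glycolysis and hypoxia genes (adjusted p = 0.030, median -0.14) were lower. Macrophage markers (adjusted p = 1.56e-04, median 1.60), ciliated cell markers (adjusted p = 5.40e-04, median 0.46) and neutrophil markers (adjusted p = 0.044, median 0.65) were higher. With an estimated correlation the adjusted p was 0.707 for the immediate early and neutrophil lists and 0.974 for the other 4. Leaving out 1 library ended 5 of the 6 calls. Without KPS-HET replicate 1 the macrophage list lay in the other direction (adjusted p = 0.495) and the glycolysis list was not called (0.807). Without KPS-HET replicate 2 the alveolar type 2 (0.643) and neutrophil (0.267) lists were not called. Leaving out KP replicate 4 ended the glycolysis (0.260), neutrophil (0.135) and ciliated (0.054) calls, KP replicate 2 the alveolar type 2 (0.211) and neutrophil (0.096) calls, and KP replicate 1 the glycolysis call (0.244). With the macrophage marker level as a term the alveolar type 2 (0.205), glycolysis (0.074) and neutrophil (0.069) lists were not called, nor was the macrophage list (0.881), which supplied the term. With the sex of the library as a term the glycolysis list was not called (0.265). Both terms were chosen after seeing the data. Among lists not called, median and mean differed in sign for alveolar type 1, club, lung transcription factor, interferon, NOTCH and fatty acid genes. The test went against both for transitional, NRF2 and neuroendocrine genes.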

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

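The test for a library far from its group was fixed in advance, and no explanation was weighed for the values it picked out. It was applied to the 4 KP libraries, for 136 values of named genes and lists, and asks whether the gap of the highest or lowest library to its nearest neighbour over the group's range exceeds Dixon's 95% critical value. For normally distributed values chance flags about 1 in 20 groups, and 10 of 136 values passed. A gene with counts in only 1 KP library is always flagged, however few they are. That rate therefore does not apply to Chgb and Chga.

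KP replicate 3 stood above the other KP libraries for Id2 (930 CPM, others 370 to 381 CPM), Gpr128 (61.6 CPM, others 6.32 to 14.1), Mpi (72.4 CPM, others 53.1 to 54.0), Ppyr1 (1.03 CPM, others 0 to 0.126) and Chgb (0.230 CPM, others 0). KP replicate 1 stood above the others for F5 (1.95 CPM, others 0 to 0.172). KP replicate 2 stood above them for Chga (0.422 CPM, others 0) and Cd79b (9.28 CPM, others 8.29 to 8.44). KP replicate 4 stood above them for G6pdx (179 CPM, others 131 to 137) and for the basal and squamous list (mean log2 CPM 1.74, others 1.23 to 1.26).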

How the results depend on the processing

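The fits with a macrophage term or a sex term and the thinned counts were chosen after seeing the data. Of 97 named genes between KPS and KP, 92 were called, and 27 of these were called under every alternative chosen in advance that tested them (the strict filter tested 92 of the 97, without Neurod1 and Tff2). Between KPS and KPS-HET none of 18 was. Between KPS and KP, 2280 genes were called with DESeq2 and 295 with the macrophage term, and 505 to 886 without 1 library. Sex as a term gave 818 and thinning 1124. Between KPS and KPS-HET, 231 were called with the strict filter, 991 with DESeq2, 92 with the macrophage term, 15 with the libraries of those groups alone and 1 to 138 without 1 library. Leaving out a KPS-HET library leaves a lone sample, assumed to vary like the other groups. Between KPS-HET and KP, DESeq2 called 2. With an estimated correlation 0 lists were called in each comparison. With the macrophage term 6 lists were called between KPS and KP and 3 between KPS-HET and KP. Without 1 library, 4 to 12 lists were called between KPS and KPS-HET (12 without KPS replicate 2 or KPS-HET replicate 2) and 3 to 9 between KPS-HET and KP (3 without KP replicate 4).

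Smarca4 between KPS and KPS-HET passed the threshold with upper-quartile factors (-0.91), the strict filter (-0.90), DESeq2 (-0.86) and limma-voom (-0.88) and without KPS replicate 1 (-1.03, adjusted p = 0.045), and ran from -1.07 to -0.68 without 1 library. With the macrophage term the macrophage list changed direction (adjusted p = 0.973 for KPS against KP and 0.815 for KPS against KPS-HET), as did Ptprc, KPS vs KP (-0.0131), since the term was built from that list. Between KPS-HET and KP its adjusted p ran from 1.10e-14 to 0.495 without 1 library, the latter without KPS-HET replicate 1. The cause of the other differences was not tested. The neuroendocrine genes Neurod1 and Scg3 had 0 counts in KP, Chgb had 4 and Chga had 7, so their fold changes rest on few counts there.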

Other observations

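The lists of liver plasma protein and mucosal defence genes, the symbol families, the genes in this and the next paragraph, the sex and macrophage terms, and the tests of Smarca4 loss alone and of depth were chosen after the data had been seen. Plasma protein genes that the liver makes in bulk moved in both directions in KPS. Trf, transferrin, fell from 5155 ± 1830 CPM in KP (SD, n = 4) to 631 ± 80.2 CPM in KPS (SD, n = 3), Apoc1 from 192 ± 22 to 31.2 ± 10.2 CPM, and Hpn, a hepatocyte protease, from 98.8 ± 8.21 to 22.1 ± 3.29 CPM. Serping1 (log2 fold change 3.45 ± 0.41) and Cp, ceruloplasmin (2.50 ± 0.46), rose. Of 32 genes tested 9 fell and 6 rose, and the hypothesis that the list fell against all other genes gave camera p = 1.63e-06 with the preset correlation and p = 0.122 with an estimated correlation (median -2.24). The list was drawn up after Alb, F5 and Habp2 had been seen, and 2 of its 39 genes are in other lists, so the p is no independent evidence.

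Among genes of mucosal defence, Dmbt1, a mucin-like scavenger receptor, rose from 17.3 ± 11.0 to 674 ± 383 CPM, Pigr, the transporter of secreted antibodies, from 7.72 ± 3.72 to 87.1 ± 56.2 CPM, and Ccl20 from 3.86 ± 2.92 to 37.2 ± 18.1 CPM. Ccl20 lost its call without KP replicate 1, 2 or 4 or KPS replicate 2 or 3 (adjusted p = 0.051 to 0.061), and its log2 fold change of 3.27 was 3.90 without KP replicate 3. Of 29 genes tested 8 rose and 1 fell, Reg1, Reg3b, Reg3g and Ltf among those that rose. The hypothesis that they rose as a list gave p = 0.0040 with the preset correlation and p = 0.183 with an estimated correlation (median 0.24), and 12 of the 35 genes listed are in other lists. Because the list was drawn up after those 4 genes had been seen, the p is no independent evidence. Among 454 symbol families (908 tests) 2 held more calls in 1 direction than chance by Fisher's exact test. With genes of identical values counted once, Sprr genes of the cornified envelope had 4 of 6 higher (adjusted p = 0.017; 5 of 7 with Sprr2a1 and Sprr2a2, which had identical values, counted separately). Glutathione transferases of the Gstm family had 4 of 7 lower (adjusted p = 0.017). The called members of both families were as many under TMM, RLE and upper-quartile scaling. Gstm1 fell from 1091 ± 366 to 347 ± 95.8 CPM. Reads shared between the close members of both families leave single genes uncertain. Fisher's test takes the members as independent, so its adjusted p for the families may also be too small.

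For the 1134 genes called between KPS and KP, the 7 libraries were split into 4 and 3 in all 35 ways. Only the real split called as many, and the highest other called 3. Every other split mixes KP and KPS libraries, which raises the spread within a group. The smallest share this test can give is 1 of 35, so it argues against chance but cannot exclude it. Sex was unequal between groups (1 of 4 KP and 2 of 3 KPS libraries were female), but with a sex term the called genes' fold changes had a slope of 0.997 on those without it. With the macrophage term the slope was 1.02 and the median size of the log2 fold change went from 1.26 to 1.21, while the median SE went from 0.246 to 0.342. That wider error left 246 of the 1134 called. The genes had been called in the fit without either term, which favours genes that vary little within a group. Slopes near 1 were therefore likely in both fits. They cannot decide whether sex or macrophage RNA contributed to the fold changes. Smarca4 genotype stays open as the explanation the design names.

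For the macrophage markers, a second list of abundant macrophage and leukocyte genes, none of them in the first, was higher than in KP by a median of 3.78 on the log2 scale in KPS replicate 1 and 2.36 in KPS-HET replicate 1 (23 of 25 genes tested). This is consistent with macrophage RNA in the sorted cells, which a gate on cancer cells would be meant to remove. KPS-HET replicate 1 exceeded KPS replicate 2 by 1.40 in mean log2 CPM, less than the SD of their groups (1.88 in KPS-HET and 1.70 in KPS). Both SDs contain the libraries compared, so this comparison could hardly go against expression set by Smarca4 loss. Libraries of the same genotype stood far apart (3.32 and 0.662 in KPS-HET, 1.93 to 5.29 in KPS), beside an SD of 0.399 in KP. This argues against genotype as the only source of the levels. Whether Smarca4 loss also raised them cannot be told here, since the libraries are too few for their spread. Whether tumours lacking Smarca4 hold more macrophages cannot be read from sorted cells.

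For the neuroendocrine genes, deeper KPS libraries are argued against. Over the 15 members the median ratio of summed counts, KPS over KP, was 8.25, and 13 members exceeded the ratio of the summed scaled library sizes (1.02). As the summed sizes were nearly equal, the count ratios restate the rise of the list and are no independent evidence for it. Without KPS replicate 3 the median was 2.75 and without KPS replicate 1 it was 3.38, the lowest values without 1 library, and without KP replicate 3 it was 29.3. Even the deepest KPS library was 2.29 times as deep as the shallowest KP library. Which of the sorted cells these transcripts came from is left open here.

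Strain DNA carried along with the floxed allele would raise the share of calls next to Smarca4. Of 198 tested neighbours along the chromosome 13 were called (6.57%, upper 95% limit 11.0% by Clopper-Pearson), against 7.23% of all genes. This argues against a raised share of 3 times that of all genes (21.7%).

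Tumours with 1 floxed allele may show part of the same shift. In genes chosen on 2 KP libraries and read against the other 2, 11 of 12 medians lay toward KPS, and the 12 ran from -0.05 to 0.24 on the log2 scale in the genes higher in KPS and from -0.32 to -0.15 in those lower, where KPS itself ran from 0.96 to 1.58 and from -1.81 to -1.23. With all KP libraries the KPS-HET medians were 0.18 and -0.26, outside the ranges of -0.03 to 0 and -0.04 to 0.01 over 20 simulations of unchanged KPS-HET libraries. Those simulations start from the KP means on which the genes had been called, so they leave out the shift that this choice alone gives. Because 1 of the medians free of that choice went the other way and the halvings share libraries, a partial shift and no shift cannot be told apart here.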
